A study of Mus musculus with 6 samples.

How the data were processed

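Total RNA of C2AS12 cells, a mouse myoblast line, was labelled with biotin and hybridised by the submitters to 6 oligonucleotide arrays whose probe sets lie near the 3' end of transcripts. The cells had been infected with adenovirus for wild-type p300 without or with doxycycline, or for mutant p300, and were taken at 0 h and after 24 h in low-serum differentiation medium. The deposited values are array signals in linear intensity for each probe set. The submitters' processing notes name MAS5; its version and settings are not given in the sources used here. The deposited table held 12488 probe sets and no detection calls. The trimmed means (2nd to 98th percentile) of the 6 arrays agreed at 199.9, within the limit of 5% set before, so the values were used as deposited.

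The 66 control probe sets were left out, which left 12422. Gene symbols came from the probe annotation provided with the data and from a reference annotation of the mouse assembly GRCm38.p6, used for names only, so no coordinates are given. Of the 12422, 10833 had 1 symbol, 396 several and 1193 none. Probe sets with a mean signal over the 6 arrays at or above the median of that mean (75.2) were tested, 6212 in all, of which 5620 had 1 symbol, 223 several and 369 none. They covered 4822 genes, and 1153 of them had a name that does not end in plain _at, which marks possible cross-hybridisation or a relaxed design. Values below the 25th percentile of all values (16.4) were set to it and log2 was taken. Where a gene had several probe sets, that with the highest mean signal stood for it. Of 701 genes with more than 1 tested probe set, 221 had time changes of opposite sign between probe sets, 0 of which were called both ways, and 245 had differences at 24 h of opposite sign. Among 27 named genes with more than 1 tested probe set, the time changes differed in sign for Mki67, Slpi, Tmem214, Rbfox2 and Hspa4, and the differences at 24 h for Tnnt1, Itga7, Pik3ca, Hspa4, Fkbp4 and Bmp4.

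Arrays were grouped by treatment (wild-type p300, wild-type p300 with doxycycline, mutant p300) and time, with 1 array for each. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, 2-sided), with jsonlite 2.0.0 for reading labels, and Benjamini-Hochberg adjustment ran over all probe sets tested. A probe set was called at an adjusted p under 0.05. The time effect was fitted with treatment as a block, so its residual (2 degrees of freedom) was the spread of the change over the 3 treatments. The outcome effect over both times set wild type against the other treatments with time as a term (3 residual degrees of freedom), which takes the arrays of a treatment at both times as independent. The outcome effects at 24 h and at 0 h and their difference, the interaction, came from a fit with 1 mean for each outcome and time. Its 2 residual degrees of freedom came from the doxycycline and mutant arrays, and the lone wild-type array was assumed to vary like them. The series description speaks of biological replicates, but the labels name no separate cultures of a treatment and time, so p-values measure only the spread between these samples. Treatment, culture and infection cannot be separated. The counts of probe sets at least 2-fold apart from both other arrays of a time, and the comparison of doxycycline with mutant p300, used no test. Because both ratios share the wild-type array, they were compared with 100 simulations in which that array was the only link. Noise was drawn from the differences of the doxycycline and mutant arrays of the same time, within 20 bins of like signal. This replaced, after the values were seen, a simulation with a spread pooled over both times, which gave lower counts (a mean of 4.82 higher and 4.86 lower at 24 h, at most 14 and 12) and put the observed 24 lower above its range.

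The analysis plan, alternatives, gene lists and named-gene rule were written before the data were examined. The 28 lists held 886 genes: myogenic regulators, muscle structure and metabolism, S phase, G2 and mitosis, cyclin-dependent kinase inhibitors and exit, pro-apoptotic and anti-apoptotic genes, p53 targets, the IGF system, interferon response, endoplasmic reticulum stress and amino acid response, heat shock, inflammatory and NF-kB genes, matrix and smooth muscle-like genes, cholesterol and fatty acid synthesis, immediate early genes, acetyltransferases and coactivators, glycolysis and hypoxia, TGF-beta, BMP and Notch, oxidative stress and metal, ribosomal proteins, oxidative phosphorylation, proteasome, and markers of adipocytes, bone and cartilage, macrophages and leukocytes, endothelium and epithelium. The 24 lists with at least 4 measured genes were tested with camera (preset correlation 0.01, 2-sided, adjusted over the lists), with an estimated correlation beside it. For single arrays a list's median was placed among 10000 random lists of the same size and like signal. A Fisher's exact test of lists among genes 2-fold apart was added after the values were seen. Named genes had 1 symbol. They were the 12 highest and 12 lowest called time changes of the same direction in all treatments, the 12 genes most clearly higher and lower in wild type than in both other arrays at 24 h and 5 each at 0 h, and the 6 highest and lowest called over both times or in the interaction. The rule added 3 each way for doxycycline against mutant p300 at each time, up to 4 genes each way from each list, and genes named in advance (Ep300, Crebbp, Kat2b, Myod1, Myog, Ckm, Cdkn1a, Bcl2, Bcl2l1, Bax and Igf2, with the rest not reported here).

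Alternatives were median centring and quantile normalization, no filter and a filter at the 75th percentile, a floor at 1 and at the median, no variance trend, each array left out, no treatment block, a 1.5-fold requirement, other fold thresholds, the mean over a gene's probe sets, and an estimated correlation. A setting with only plain _at probe sets, and scaling of each array to the same mean log2 signal of 9 spike-in controls, were added after the data were seen. The pipeline was tested on simulated data with known changes. Of 2-fold changes it recovered 88.1% for time, 79.1% for outcome over both times and 56.7% for outcome at 24 h. The false calls were 16 of 169, 4 of 153 and 7 of 122. For lists shifted by 0.5 over time the set test recovered 10 of 10 with the preset correlation and 0 of 10 with an estimated correlation, with 0 false calls for both. A later run, added after the values were seen, covered 3 fits and shifts of 0.5, 1, 2 and 3 with independent genes. The preset correlation recovered 10 of 10 each time, with at most 1 false call among 90 unchanged lists. The estimated correlation recovered 0, 0, 10 and 10 for time, 9, 10, 10 and 10 for outcome over both times and 0, 0, 9 and 10 for outcome at 24 h, with 0 false calls. Genes were independent in both runs, so the false calls do not show how the preset 0.01 behaves in correlated lists. In the real lists the correlation estimated over time ran from -0.04 (myogenic regulators) to 0.415 (cholesterol and fatty acid synthesis). For G2 and mitosis it was 0.287. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.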

Results

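Gene expression was measured in C2AS12 cells, a myoblast line derived from mouse C2 cells, on 6 oligonucleotide arrays of total RNA. The cells carried adenovirus for p300, a histone acetyltransferase and transcriptional coactivator, in 3 treatments: wild-type p300, wild-type p300 with doxycycline, and mutant p300. Each treatment was measured at 0 h, before the change to low-serum differentiation medium, and after 24 h in it, with 1 array for each treatment and time. The submitters give survival as the outcome with wild-type p300 and apoptotic death with both other treatments. The labels state neither the mutation nor what doxycycline does in these cells. The trimmed mean signal was 199.9 on each array and the median signal lay between 68.7 and 78.0. The mean log2 signal of 9 spike-in controls, relative to the mean of the 6 arrays, was -0.18 in the wild-type array at 24 h, 0.13 and 0.23 in the doxycycline and mutant arrays at 24 h and -0.13 to -0.02 in those at 0 h. Scaling to these controls, tried after the values were seen, moved most of the counts. Between 23.3% and 26.5% of the probe sets of an array lay under a signal of 16.4, which served as the floor. No treatment had a replicate array at the same time, so the number of arrays limits the precision. The series description counts the 6 arrays as biological replicates, and whether an array holds a single culture or a pool is not stated. The first principal component held 52.1% of the variance and parted the times. The second held 21.3% and set both wild-type arrays, at 10.4 and 20.4, apart from the other 4, at -13.7 to -1.65.

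The comparison of 24 h with 0 h asked what changed over 24 h in differentiation medium across the 3 treatments. No array was taken at 24 h without the medium change, so medium and time in culture cannot be told apart. A call bears on the mean change and does not mean that the 3 treatments changed equally. By limma, 16 of 27 genes of muscle structure and metabolism rose, and 33 of 33 genes of G2 and mitosis and 23 of 26 S phase genes fell. Myog, the transcription factor that drives late myogenic differentiation, rose by 2.20 ± 0.04 on the log2 scale (mean of the changes in the 3 treatments; SD, n = 3; limma adjusted p = 0.000119). Mki67, a marker of cycling cells, fell by 4.48 ± 0.69 (adjusted p = 2.47e-05). Of 6212 probe sets tested, 450 rose and 559 fell, and 55 and 153 of these changed at least 2-fold. The calls stood for 384 genes that rose and 467 that fell. Without the filter on dim probe sets limma called 0, with 2030 of 12422 probe sets at an unadjusted p under 0.05. With scaling to the spike-in controls 141 rose and 478 fell. The count was 556 without the doxycycline array at 0 h, 481 without the mutant array at 0 h, 539 without the doxycycline array at 24 h and 479 without the mutant array at 24 h.

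Among genes of muscle structure and metabolism, 16 of 27 measured rose, 1 fell and 10 did not pass the test. Adjusted over the list alone, 17 rose and 1 fell. Tnnt1, the slow skeletal troponin T, rose by 2.71 ± 0.43, and a second probe set of it read between 87.5 and 167.1 on all arrays. Myl1, a fast myosin light chain, rose by 2.68 ± 0.50, Ryr1, the calcium release channel of the sarcoplasmic reticulum, by 1.91 ± 0.31, and Acta1, skeletal actin, by 1.15 ± 0.36. Eno3, the muscle enolase, fell by 0.72 ± 0.17. The set test (camera) put the list higher at 24 h, with adjusted p = 1.78e-08, and adjusted p = 0.262 with an estimated correlation. Of 11 myogenic regulators, 5 rose and 0 fell by limma, against 6 and 0 adjusted over the list alone; 6 did not pass. They included Six4 at 0.92 ± 0.21, Itga7 at 0.50 ± 0.11 and Mef2a at 0.46 ± 0.16. Their set test gave adjusted p = 0.00641, and adjusted p = 0.262 with an estimated correlation. Myod1, the myogenic determination factor, was not called, with a change of 0.06 ± 0.32. Of 8 genes of the IGF system, 4 rose, 0 fell and 4 did not pass, and adjusted over the list alone 5 rose and 1 fell. Igf2, a growth factor made by differentiating myoblasts, rose by 1.39 ± 0.23, Pik3ca by 0.92 ± 0.41 and Igf1r by 0.69 ± 0.08. A second probe set of Igf2, left out by the filter, read between 2.7 and 6.5 on all arrays, under the floor. The set test gave adjusted p = 0.00524, and adjusted p = 0.262 with an estimated correlation.

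All 33 measured genes of G2 and mitosis fell, and their median change was -2.76. Besides Mki67 these included Kif20a, a kinesin of cytokinesis, at -4.32 ± 1.20, Top2a, a topoisomerase, at -4.06 ± 0.57, and Aurkb, a mitotic kinase, at -3.90 ± 0.10. Several of these genes reached the floor at 24 h, so that their change is bounded by it; Mki67 read 6.8, 44.3 and 19 in the wild-type, doxycycline and mutant arrays. A second probe set of Mki67 read between 49.6 and 88.3 on all arrays. Of 26 S phase genes, 23 fell, 0 rose and 3 did not pass, with a median change of -1.23. Uhrf1 fell by 2.91 ± 0.66, the replication helicase subunit Mcm5 by 2.69 ± 0.55 and the ribonucleotide reductase subunit Rrm2 by 2.53 ± 0.78. Adjusted over the list alone, the counts were again 33 and 23. The set tests gave adjusted p = 5.7e-37 for G2 and mitosis and 9.62e-17 for S phase, and adjusted p = 0.262 with an estimated correlation for both. In simulated data with independent genes that setting recovered 10 of 10 lists shifted by 2 or 3 over time and 0 of 10 shifted by 0.5 or 1. The estimated correlation was 0.287 for G2 and mitosis and 0.186 for S phase, against the preset 0.01. Lists with an estimated correlation under the preset, such as myogenic regulators (-0.04) and glycolysis and hypoxia (-0.035), also came to adjusted p = 0.262. A correlation above the preset was thus not needed for a set call to be lost. Neither setting was simulated with correlated genes, so how each behaves in correlated lists was not tested. Further members with large changes were Bub1, Ect2, Birc5, Smc2 and Ttk, which fell by 3.13 to 3.54 on the log2 scale. Outside these lists, Anln, a scaffold of the cleavage furrow, fell by 4.03 ± 0.38, Nusap1 by 3.43 ± 0.28 and D17H6S56E-5 fell by 3.32 ± 0.41. Of 15 cyclin-dependent kinase inhibitors and exit genes, 4 rose, 3 fell and 8 did not pass (set test adjusted p = 0.126), and adjusted over the list alone 5 rose and 3 fell. Gadd45a rose by 1.22 ± 0.28 and Cdkn1a, which encodes the inhibitor p21, by 0.65 ± 0.24, while Cdkn2d fell by 2.16 ± 1.42 and the pocket protein gene Rbl1 by 1.24 ± 0.17.

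Matrix genes rose in part. Of 34 genes of the extracellular matrix and smooth muscle-like state, 10 rose, 1 fell and 23 did not pass, and adjusted over the list alone 12 rose and 2 fell. Dcn, the proteoglycan decorin, rose by 2.06 ± 0.41, Tnc, tenascin C, by 1.21 ± 0.08 and Col6a1, a collagen VI chain, by 0.97 ± 0.14. As a set they had adjusted p = 0.000202, and adjusted p = 0.262 with an estimated correlation. Of 17 genes of TGF-beta, BMP and Notch signalling, 7 rose, 3 fell and 7 did not pass (set test adjusted p = 0.146), and adjusted over the list alone 9 rose and 4 fell. The inhibitors of myogenic factors Id2, Id1 and Id3 fell by 1.76 ± 0.48, 1.21 ± 0.21 and 0.84 ± 0.23. The Notch ligand gene Dll1 rose by 1.18 ± 0.17. Outside the lists, Apoe, apolipoprotein E, was at the floor on all 3 arrays at 0 h and read 109.2, 290.4 and 119.6 at 24 h, at least 6.66-fold, 17.7-fold and 7.29-fold higher with wild-type p300, doxycycline and mutant p300. Car3, a muscle carbonic anhydrase, rose by 1.78 ± 0.50, Adh1 by 1.86 ± 0.65, Klk1b22 by 1.76 ± 0.05, Ogn by 1.74 ± 0.35 and Mtss2 by 1.53 ± 0.74. Aldh1a1 rose by 1.94 ± 1.58, from 40 to 463.7 in wild type, from 18.5 to 69.8 with doxycycline and from 32.3 to 41.7 with mutant p300.

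In 7 lists of metabolism, protein turnover and stress, between 3 and 11 genes fell and most did not pass the test. Of 33 genes of the endoplasmic reticulum stress and amino acid response, 2 rose, 11 fell and 20 did not pass, and adjusted over the list alone 2 rose and 12 fell. Among those that fell were Mthfd2, an enzyme of folate metabolism, at -1.80 ± 0.35 and Asns, asparagine synthetase, at -1.65 ± 0.08, while the stress sensor gene Atf6 rose by 0.93 ± 0.34. Camera gave this set adjusted p = 3.43e-05, and adjusted p = 0.262 with an estimated correlation. Of 21 genes of oxidative stress and metal response, 8 fell, 0 rose and 13 did not pass (10 fell adjusted over the list alone), with Gclm at -1.36 ± 0.05 and Nqo1 at -1.35 ± 0.58. For the whole list, camera gave adjusted p = 4.85e-05, and adjusted p = 0.262 with an estimated correlation. Of 20 genes of cholesterol and fatty acid synthesis, 7 fell, 0 rose and 13 did not pass, and adjusted over the list alone 11 fell and 1 rose. Idi1 fell by 1.41 ± 0.62 and Fdps by 0.70 ± 0.24. The set test gave adjusted p = 2.43e-05, and adjusted p = 0.367 with an estimated correlation. Of 22 genes of glycolysis and hypoxia, 8 fell, 0 rose and 14 did not pass, with the same counts adjusted over the list alone. Pgam1 fell by 0.78 ± 0.15 and Ldha by 0.70 ± 0.08. As a set they had adjusted p = 0.00596, and adjusted p = 0.262 with an estimated correlation. Of 33 proteasome genes, 8 fell, 0 rose and 25 did not pass (18 fell adjusted over the list alone), with Psmd14 at -0.63 ± 0.14. Of 56 genes of oxidative phosphorylation, 10 fell, 0 rose and 46 did not pass (10 fell adjusted over the list alone), with Ndufb8 at -0.68 ± 0.04. Their set tests gave adjusted p = 9e-06 and 0.00015, and adjusted p = 0.262 with an estimated correlation for both. Of 24 ribosomal protein genes, 3 fell, 0 rose and 21 did not pass, with the same counts adjusted over the list alone, and with Rpsa at -0.54 ± 0.29. Camera gave this set adjusted p = 0.0144, and adjusted p = 0.566 with an estimated correlation.

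Against 384 of 4822 genes that rose and 467 that fell, the lists of cell death were called as follows. Of 21 pro-apoptotic genes, 4 rose, 0 fell and 17 did not pass, and adjusted over the list alone 6 rose and 2 fell. Bcl2l11, which encodes the BH3-only protein Bim, rose by 1.01 ± 0.10, the inflammatory caspase gene Casp4 by 0.68 ± 0.11 and Pdcd4 by 0.51 ± 0.34. The median of the list was -0.07 and its mean 0.07, and the set test gave adjusted p = 0.59. Of 15 anti-apoptotic genes, 1 rose, 2 fell and 12 did not pass (the same adjusted over the list alone; set test adjusted p = 0.815). Birc2, an inhibitor of apoptosis protein, rose by 0.65 ± 0.42 and Pea15a fell by 0.77 ± 0.55. Bcl2 at 0.08 ± 0.20 and Bcl2l1 at 0.16 ± 0.11 were not called. Of 17 p53 target genes, 5 rose, 2 fell and 10 did not pass, and adjusted over the list alone 6 rose and 2 fell. Sesn1 rose by 0.69 ± 0.10, Pltp by 0.67 ± 0.03 and Btg2 by 0.69 ± 0.14, and Gtse1 fell by 1.17 ± 0.29. For the whole list, camera gave adjusted p = 0.021, and adjusted p = 0.367 with an estimated correlation. Of 22 immediate early genes, 4 rose, 2 fell and 16 did not pass, and adjusted over the list alone 6 rose and 3 fell. Zfp36l1 rose by 1.09 ± 0.14 and Egr1 by 0.73 ± 0.15, and Fosl1 fell by 1.32 ± 0.23. The set test gave adjusted p = 0.0377, and adjusted p = 0.262 with an estimated correlation.

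The set tests of the remaining lists passed no threshold for time. Of 17 heat shock genes, 2 rose, 4 fell and 11 did not pass (3 and 4 adjusted over the list alone; set test adjusted p = 0.98), with Hspa1b at 0.48 ± 0.18 and the mitochondrial chaperone gene Hspd1 at -0.66 ± 0.24. Of 22 inflammatory and NF-kB genes, 2 fell and 0 rose by limma, and 0 were called adjusted over the list alone (set test adjusted p = 0.654). Those 2 were Ccl7 at -0.89 ± 0.71 and Cxcl5 at -0.57 ± 0.34. Ccl7 changed by -0.078 with wild-type p300, -1.353 with doxycycline and -1.24 with mutant p300. Of 20 interferon response genes, 1 fell, Ifi204 at -0.41 ± 0.08, and 0 were called adjusted over the list alone (set test adjusted p = 0.405). The list of acetyltransferases and coactivators also holds histone deacetylase genes. Of its 13 measured genes, 3 rose, 1 fell and 9 did not pass (4 and 1 adjusted over the list alone, set test adjusted p = 0.319). Crebbp, the paralog of p300, rose by 0.59 ± 0.19 and Kat2b by 0.52 ± 0.10. Of the deacetylase genes, Hdac5 rose by 0.65 ± 0.37 and Hdac3 fell by 0.45 ± 0.28. No probe set was assigned to p300 itself (Ep300) alone, nor to Bax, and Ckm lay under the filter.

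**Figure D1:**
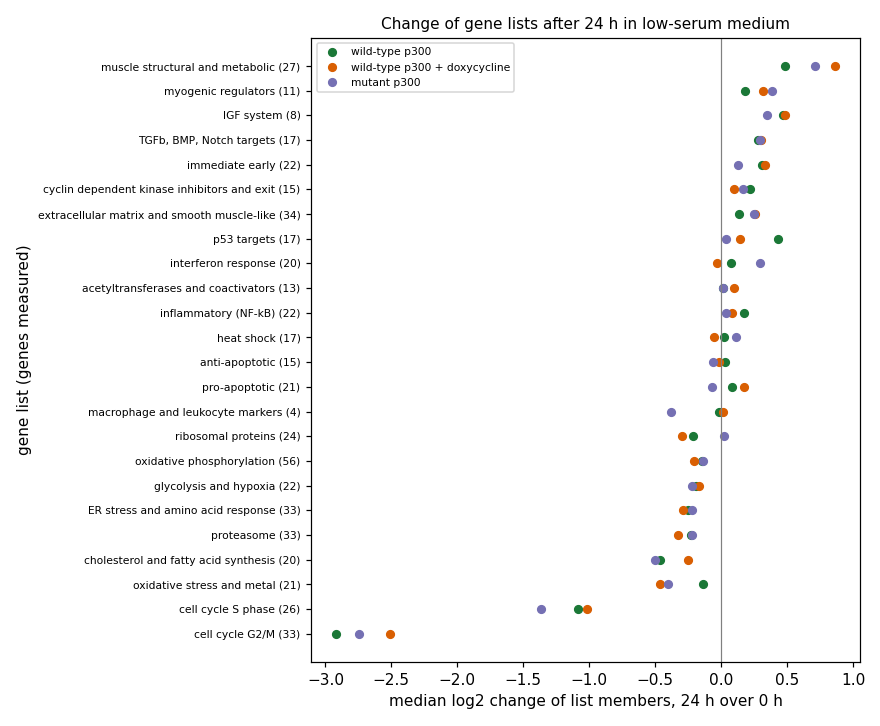
Median log2 change of each gene list from 0 h to 24 h (horizontal axis), with 1 point for each treatment and the number of genes measured in brackets; there are no replicates and no error bars. The list of G2 and mitosis lay lowest and the list of muscle structure and metabolism highest in all 3 treatments.

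The comparison of the wild-type array with the doxycycline and mutant arrays at 24 h asked which genes go with survival. By limma, 2 of 22 inflammatory, 4 of 21 oxidative stress and 1 of 34 matrix genes were higher with wild-type p300. Ccl2, the monocyte chemokine MCP-1, read 1773.7 with wild-type p300, 150.7 with doxycycline and 217.6 with mutant p300, a log2 difference of 3.29 (limma adjusted p = 0.00563). Hsd11b1, the enzyme that activates glucocorticoids, read 586.0, 46.1 and 50.6 in the same order, a difference of 3.60 (adjusted p = 0.0218). Kif20a was lower with wild-type p300, at 11.6 against 74.9 and 69.2, a difference of -2.13 with the floor applied (adjusted p = 0.00742), and a second probe set of it read 20.6 against 43.1 and 32.9. Of 6212 probe sets, 45 were higher and 3 lower in the wild-type array, for 38 and 3 genes; at an unadjusted p under 0.05 there were 367 higher and 346 lower. The count rested on 1 wild-type array, whose spread was taken from the other treatments, and was 11 without the variance trend and 192 without the filter, with 6 of the 48 among the 192. With scaling to the spike-in controls it was 426 (420 higher, 6 lower), 47 of the 48 among them. It was 161 without the doxycycline array at 0 h (129 higher, 32 lower), 163 without the mutant array at 0 h (131 and 32), 200 without the doxycycline array at 24 h (145 and 55) and 351 without the mutant array at 24 h (244 and 107). The 3' to 5' ratio of the actin control probe sets, a sign of RNA quality, was 1.33 in the wild-type array and 1.45 and 1.49 in the others at 24 h, against 1.30 to 1.34 in the arrays at 0 h. The same ratio for Gapdh did not set the wild-type array apart at 24 h. It was 0.875 there, 0.859 with doxycycline and 0.905 with mutant p300.

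Further genes higher in the wild-type array at 24 h were called by limma: Anxa8 by 2.78 (adjusted p = 0.00596), Ccl7, a second monocyte chemokine, by 2.47 (0.00849), the acute phase gene Lbp by 2.44 (0.00849) and the adaptor gene Blnk by 2.28 (0.00596). Slpi, a protease inhibitor, was higher by 2.97, Slfn2 by 2.79, Aldh1a1, a retinaldehyde dehydrogenase, by 3.10 and Igll1 by 2.51, with adjusted p between 0.0327 and 0.0497. Sprr1a (687.5 against 47.9 and 77.3) and Tinagl1 (169.1 against 20.4 and 35.2) stood at least 2-fold apart and missed the threshold, with adjusted p = 0.0609 and 0.0512. Kif20a was the only one of the 12 genes most strongly lower in the wild-type array that was called. The other 11 were Sema6c, Hyal2, Kat2a, Llgl2, Ncf4, Chaf1a, Cavin2, Tnk2, Pspn, Tmem214 and Ptprcap, with adjusted p between 0.0633 and 0.348. Kat2a, which encodes the acetyltransferase GCN5, read 42.2 against 116.9 and 145.4, and Chaf1a, a subunit of the chromatin assembly factor, 21.6 against 62.6 and 54.7. The wild-type value of Kif20a lay under the floor, and with the floor at the median its call was lost. The name of its probe set does not end in plain _at, so the setting with only those left it out.

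**Figure D2:**
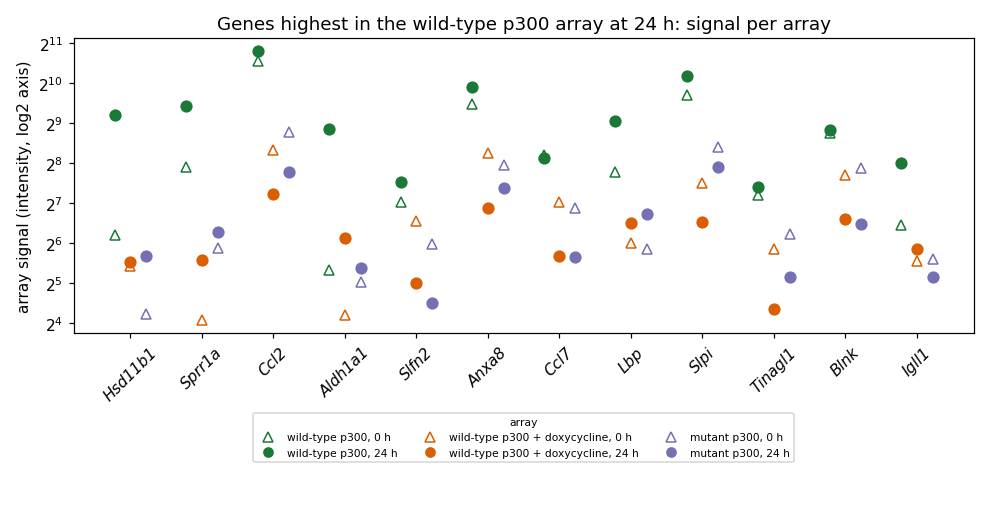
Array signal (intensity, log2 axis) of the 12 genes most strongly higher in the wild-type p300 array than in both others at 24 h, each point 1 array, open triangles at 0 h and filled circles at 24 h; there are no replicates. Ccl2 stood at 1487.0 in the wild-type array at 0 h, against 321.1 and 441.5, and at 1773.7 at 24 h, against 150.7 and 217.6.

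By the gene lists, 22 inflammatory and NF-kB genes were higher as a set in the wild-type array at 24 h with adjusted p = 5.37e-05, and adjusted p = 0.477 with an estimated correlation. Of these 2 were called higher (Ccl2 and Ccl7), 0 lower and 20 did not pass, and adjusted over the list alone 8 were higher and 1 lower. Of 21 genes of oxidative stress and metal response, 4 were higher, 0 lower and 17 did not pass, with 4 and 1 adjusted over the list alone. Srxn1, sulfiredoxin, read 627.0 against 76.6 and 167.1, Gsta2, a glutathione transferase, 611.5 against 174.2 and 178.6, Nqo1 643.4 against 247.9 and 293.5, and Gsta4 1057.9 against 451.5 and 505.6. Camera gave this set adjusted p = 0.00141, and adjusted p = 0.477 with an estimated correlation. These 4 were also at least 2-fold above both other arrays, as were 66 of 4822 genes, a one-sided Fisher's exact p = 0.000161 (adjusted over 48 comparisons 0.00772; test added after the values were seen). No other list passed this test, in which inflammatory genes had 3 of 22 and matrix genes 3 of 34. Genes of a list are not independent, so the Fisher p is too small. With 1 wild-type array it does not measure the spread between cultures. Of 17 heat shock genes, 1 was higher, the small heat shock protein gene Cryab at 773.7 against 152.8 and 235.2, and 2 were adjusted over the list alone. For the whole list, camera gave adjusted p = 0.00112, and adjusted p = 0.477 with an estimated correlation. Of 34 matrix genes, 1 was higher, the collagen VI gene Col6a3 at 2868.4 against 1256.7 and 1281.4, and 6 were higher and 1 lower adjusted over the list alone. The set test gave adjusted p = 0.0246, and adjusted p = 0.477 with an estimated correlation. Fbln2, Tnc and Ptgs2 stood at least 2-fold above both arrays without passing the test, with adjusted p = 0.0732, 0.135 and 0.175.

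Of 22 immediate early genes, 1 was higher at 24 h, the phosphatase gene Dusp1 at 1041.4 against 452.6 and 478.2, and 3 were adjusted over the list alone. As a set they had adjusted p = 0.0169, and adjusted p = 0.541 with an estimated correlation. The 17 p53 target genes were higher as a set with 0 called by limma, also adjusted over the list alone, and a median of 0.29. Camera gave this set adjusted p = 0.0157, and adjusted p = 0.477 with an estimated correlation. The 33 genes of G2 and mitosis were lower as a set in the wild-type array with a median of -0.36 (0 with scaling to the spike-in controls) and 1 called, Kif20a. For the whole list, camera gave adjusted p = 0.00641, and adjusted p = 0.716 with an estimated correlation. Many of these genes lay near the floor at 24 h. Of 33 genes of the endoplasmic reticulum stress and amino acid response, 2 were called higher, Nupr1 at 536.4 against 198.1 and 208.8 and Psat1, an enzyme of serine synthesis, at 1631.9 against 499.0 and 754.0 (set test adjusted p = 0.0947). The other 16 lists tested had set tests at adjusted p = 0.0893 or above. Chrnb1, of the muscle list, at 140.7 against 375.7 and 292.4, and Mcm5, of the S phase list, at 49.9 against 106.0 and 102.7, stood 2-fold below both arrays, with adjusted p = 0.0842 and 0.0857. For 24 h the actin 3' to 5' ratio of 1.33 in the wild-type array, against 1.45 and 1.49, and the spike-in signal of -0.18, against 0.13 and 0.23, hold beside each of these groups. Of 10 epithelial markers, Cldn3 (84.9 against 40.4 and 33.7), Cldn4 (72.9 against 15.2 and 30.5) and Krt8 (45.9 against 10.4 and 20) were also at least 2-fold higher in that array, all under the filter; a second probe set of Cldn3 read 11.8 against 15.1 and 15.4.

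Over both times, 31 probe sets were higher and 2 lower in the wild-type arrays by limma, and 22 of the 31 were among the 45 at 24 h. At an unadjusted p under 0.05 there were 433 higher and 419 lower. Sprr1a, a precursor of the cornified envelope, was higher by 3.21 (adjusted p = 0.0232), Ccl2 by 2.64 (0.00695), Slpi by 2.36 (0.0456), Lbp by 2.15 (0.00695), Anxa8 by 2.08 (0.0201) and Ccl7 by 1.86 (0.025). Tmed4, a gene of vesicle transport, was lower by a log2 difference of -0.63 (0.046). The measured genes named in advance were not called. Of these, Igf2 had a difference of -0.74, Myod1 of -0.60 and Bcl2 of 0.40 (limma adjusted p = 0.0555, 0.125 and 0.27). Igf2 read 117.2 against 224.9 and 223.5 at 0 h and 369.6 against 543.8 and 531.9 at 24 h, and a second probe set of it lay under the floor on all arrays. Bcl2 read 295.1 against 199.4 and 199.1 at 24 h, and a second probe set of it 160 against 135.6 and 159.6. In the lists, Cryab at 1.71, Col6a3 at 0.97, Tnc at 1.24, Col4a2 at 0.71, Gsta2 at 1.37, Nupr1 at 1.06 and Dusp1 at 0.88 were called higher. The set tests gave adjusted p = 1.31e-05 for inflammatory, 2.69e-05 for heat shock, 0.000559 for matrix, 0.00342 for oxidative stress and 0.0435 for p53 target genes, all higher, and adjusted p = 0.304 with an estimated correlation for each. Immediate early genes were higher with adjusted p = 0.0161 (adjusted p = 0.416 with an estimated correlation), and genes of G2 and mitosis lower with 0.00123 (adjusted p = 0.577 with an estimated correlation). In simulated data with independent genes the estimated correlation recovered 9 of 10 lists shifted by 0.5 in this fit and 10 of 10 shifted by 1. The medians of these 7 lists lay between -0.24 and 0.32, a size that was not simulated, and their set calls rest on the preset correlation. The wild-type arrays are 1 treatment at 2 times and the other 4 are 2 treatments, and the fit takes the arrays of a treatment as independent. The count of 33 was 1 without the variance trend and 10 without the filter, with 0 of the 33 among the 10. With scaling to the spike-in controls it was 237 (227 higher, 10 lower), 32 of the 33 among them. It was 0 without the wild-type array at 24 h (258 at an unadjusted p under 0.05), 15 without the doxycycline array at 0 h, 15 without the mutant array at 24 h and 50 without the doxycycline array at 24 h.

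At 0 h, before the medium was changed, limma called 0 probe sets for wild type against the other treatments, with 262 at an unadjusted p under 0.05, where 311 would be expected by chance. The count was 126 without the filter, 5 with scaling to the spike-in controls, 18 without the doxycycline array at 0 h, 24 without the mutant array at 0 h, 36 without the doxycycline array at 24 h and 38 without the mutant array at 24 h. Genes with the strongest separation from both arrays at 0 h, none of them called, were Sprr1a (237.7 against 16.8 and 58.7), Lbp (219.2 against 64.0 and 58.0), Ccl2, Baiap2l1 (113.0 against 38.7 and 40.3) and Lama4 (137.9 against 54.4 and 54.3). On the lower side were Lst1 (24.1 against 128.0 and 111.9), Pcsk7 (23.9 against 105.7 and 106.0), Rbfox2 (39.1 against 176.3 and 151.5), Cdc42ep4 and Ppp2r5d. Whether the response over 24 h differed between wild type and the others was tested as an interaction, for which limma called 0 probe sets, with 197 at an unadjusted p under 0.05. That count was 245 without the filter, 1 with scaling to the spike-in controls, 11 without the doxycycline array at 0 h, 6 without the mutant array at 0 h, 6 without the doxycycline array at 24 h and 43 without the mutant array at 24 h.

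Counts of single arrays showed how far each array stood from the other arrays of its time, with no test. At 24 h, 81 probe sets were at least 2-fold higher and 24 at least 2-fold lower in the wild-type array than in both others. The same count gave 11 and 28 for the doxycycline array and 7 and 34 for the mutant array. At 0 h it gave 21 and 11 for wild type, 6 and 18 for doxycycline and 2 and 14 for mutant. With the floor at the median, wild type at 24 h had 77 higher and 6 lower, and the totals for doxycycline and mutant were 20 and 12. With the filter at the 75th percentile these were 35 and 3, and 10 and 1. Without the filter wild type had 225 higher and 90 lower, and the totals were 213 and 216. With scaling to the spike-in controls it had 216 higher and 6 lower, and the totals were 33 and 79. Of the 81, 77 were also highest in the wild-type array at 0 h (95.1%, 95% exact interval 87.8% to 98.6%), against 32.1% of all probe sets tested. Probe sets are not independent, so the interval is too narrow. Taken pair by pair at 24 h, 165 probe sets were 2-fold higher and 79 lower in wild type than with doxycycline, and 159 higher and 55 lower than with mutant p300. Both ratios share the wild-type array. In 100 simulations with the shared array as the only link and the spread of the doxycycline and mutant arrays of that time, a mean of 16.5 and at most 26 probe sets were higher in both at 24 h, and a mean of 17.3 and at most 26 were lower. The 81 higher lay above that range and the 24 lower within it. In an earlier simulation, with the spread pooled over both times, at most 14 were higher and at most 12 lower, so that the 24 lay above it; whether the 24 exceed the effect of the shared array is open. At 0 h at most 18 were higher and at most 18 lower, against 21 and 11. The correlation of the ratios across probe sets, which are not independent replicates, was 0.621 against a simulated 0.5 at 24 h, and 0.572 against 0.504 at 0 h. With 1 wild-type array per time, the shared array could not be split.

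**Figure D3:**
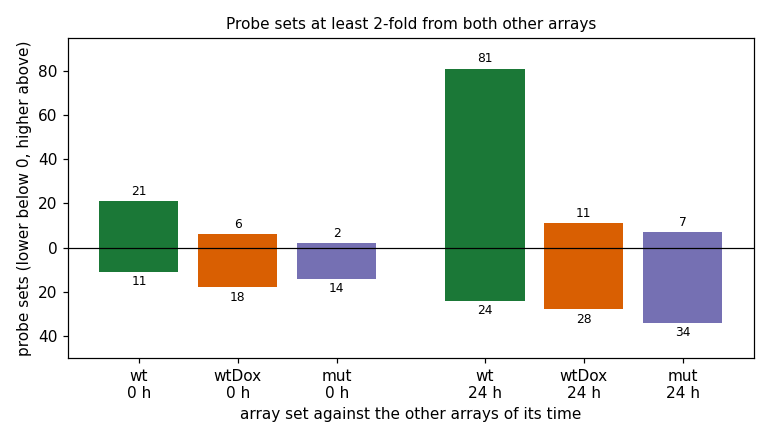
Number of probe sets at least 2-fold higher (above 0) or lower (below 0) in 1 array than in both other arrays of its time, for each array in turn; wt is wild-type p300, wtDox wild-type p300 with doxycycline and mut mutant p300. The wild-type array at 24 h had 81 higher, against 11 and 7 for the others.

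The doxycycline and mutant arrays, which share the outcome of death, also differed from each other, again with 1 array each and no test. Muscle genes were higher with doxycycline: the median log2 ratio of the 27 genes of muscle structure and metabolism over the mutant array was 0.30 at 0 h and 0.44 at 24 h, both above all of 10000 random lists of like signal. At 24 h the genes of G2 and mitosis, at 0.30, and of cholesterol and fatty acid synthesis, at 0.34, also lay above all random lists, while at 0 h they were on the other side, at -0.08 and -0.10. The 3 measured adipocyte markers had a median of 0.77 at 0 h (percentile 99.97, 3 higher and 0 lower with doxycycline). At 24 h it was 0.34 (percentile 93.9, 2 higher and 1 lower). Tnnt1 read 115.9 with doxycycline and 33.7 with mutant p300 at 0 h. Mapt, which encodes the microtubule protein tau, was low with doxycycline at both times, at 10.3 against 116.0 at 0 h and 18.9 against 248.3 at 24 h. Adgrg1, an adhesion receptor, read 18.6 against 110.3 at 0 h. Lgi4 was lower at 0 h, and Cdkn2d and Pafah2 were lower at 24 h, in the doxycycline array. Prp2 and Prkar1b were higher in the doxycycline than in the mutant array at 0 h, and Prss30, Acaa1b and Traip at 24 h. Prss30 at 24 h read 178.7 in wild type, 178.2 with doxycycline and 21.7 with mutant p300, and Prp2 at 0 h 174.4, 203.3 and 43.9. For both the mutant array was the one apart. At the other time the mutant array was higher for Prp2 (159.7 against 48.5) and Traip (89.6 against 46.9). At 24 h, 83 probe sets were 2-fold higher and 58 lower with doxycycline, against 33 and 29 at 0 h. Against the doxycycline array at 24 h, the median of the muscle list in the wild-type array was -0.40, below all of the random lists. Against the mutant array it was 0.00, at percentile 64.9.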

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

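The tests for noise, RNA quality, epithelial cells and muscle noise, and the splits by outcome, were chosen after the results they bear on had been seen; the splits by time and the test of scaling on muscle genes were planned before.

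Of 40 named genes checked, 12 moved one way over 24 h with wild-type p300 and the other way with both doxycycline and mutant p300. With 1 array each, the opposite signs were not tested gene by gene beyond the limma interaction, which gave adjusted p = 1 for these genes. The change in wild type minus the mean change in the others, on the log2 scale, was positive for 9: Ccl2 (1.31), Slfn2 (2.02), Anxa8 (1.39), Slpi (1.21), Tinagl1 (1.48), Blnk (1.33), Lst1 (2.48), Pcsk7 (2.45) and Bcl2 (0.34). It was negative for 3: Kat2a (-1.39), Cavin2 (-1.61) and Myod1 (-0.55). For Bcl2 the changes with doxycycline and mutant p300 were only -0.014 and -0.062. A second tested probe set of Bcl2 rose in all 3 treatments. It went from 126.8 to 160 in wild type, 65.9 to 135.6 with doxycycline and 106.7 to 159.6 with mutant p300. Bcl2 thus counts among the 12 by 1 of its 2 tested probe sets. Ccl2 changed by 0.25 in wild type, -1.09 with doxycycline and -1.02 with mutant p300, and Slfn2 by 0.50, -1.55 and -1.48. Ccl2, Slfn2, Anxa8, Slpi, Tinagl1 and Blnk had been chosen for a high wild-type value at 24 h, Kat2a and Cavin2 for a low value at 24 h, and Lst1 and Pcsk7 for a low value at 0 h, and each such choice favours a difference of this sign.

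The 81 probe sets at least 2-fold higher in the wild-type array than in both others at 24 h were weighed first. Noise of the single 24 h array as the cause is argued against by the separate array at 0 h, where 95.1% of them were again highest in wild type, against 32.1% of all probe sets. RNA quality as the whole cause is argued against by their median log2 ratio of 0.687 at 0 h (quartiles 0.418 to 0.975), where the log2 actin 3' to 5' ratio differed by 0.007, compared with -0.146 at 24 h. The Gapdh ratio of wild type at 24 h, 0.875, lay between 0.859 with doxycycline and 0.905 with mutant p300. Epithelial cells in the wild-type culture stay open: 3 of 10 markers were 2-fold higher there at 24 h (Cldn3 at 84.9 against 40.4 and 33.7, Cldn4 at 72.9 against 15.2 and 30.5, Krt8 at 45.9 against 10.4 and 20), while Krt18 read 22 against 26.9 and 19.9 and Cdh1 154.4 against 206.5 and 183.9, and only 1 of the 10 lay above the filter. At 0 h, where most of the 81 were already highest in wild type, Cldn3, Cldn4 and Krt8 were not 2-fold higher there. Cldn3 read 38 against 31.1 and 33.1, Cldn4 12.2 against 17.7 and 10.1, and Krt8 6 against 18.1 and 9.9. Krt14 went the other way, at 28.9 against 11.1 and 9.1. Most of these signals lay near or under the floor, so the 0 h values do not decide whether epithelial cells were present. Treatment, the explanation the design names, and any difference between the cultures cannot be told apart with 1 array for each treatment and time.

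The higher muscle genes of the doxycycline array at 24 h were weighed next. Of 27 genes, 19 were highest in that array. Noise of that array as the cause is argued against by the separate array at 0 h, where 17 of the 27 were highest (63.0%, 95% exact interval 42.4% to 80.6%, against 33.4% of all genes); genes of a list are not independent, so the interval is too narrow. For the difference from the mutant array, scaling as the cause is argued against by the median ratio over that array. It was 0.435 as deposited and at least 0.341 under median centring and quantile normalization. That test covered neither the wild-type array nor the spike-in controls. With scaling to those controls the list's median in wild type against the others at 24 h went from -0.298 to 0.067. Scaling therefore stays open for the difference from wild type. Doxycycline itself and a difference between cultures stay open and untested.

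The split of the 6 arrays by time called 1009 probe sets, and the highest of the other splits called 0, so 1 of 10 splits gave as many. Setting wild type against the others called 33 over both times and 48 at 24 h, and the same fits with doxycycline or mutant p300 set apart called at most 0, so 1 of 3 splits gave as many for each. The numbers of splits, 10 and 3, are too few for a share under 0.05. In the other splits the time effect, or the difference of the wild-type arrays, stayed wholly or in part in the residual. That lowers their calls, so the counts of 0 do not show what arrays without an effect would give.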

How the results depend on the processing

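Median centring, quantile normalization and a floor at 1 kept each count within 1.5 times its main value, and no called result reversed. Scaling to the spike-in controls, chosen after the data were seen, did not: it called 619 for time (141 higher, 478 lower), 237 for outcome over both times, 426 at 24 h, 5 at 0 h and 1 for the interaction, with 222 probe sets 2-fold apart in the wild-type array at 24 h, 79 in the mutant array and 11 lists called at 24 h. It raised the wild-type array of 24 h against the others of that time, whose spike-in signal was higher, so that the median difference of all genes at 24 h went from -0.05 to 0.31. The median of G2 and mitosis at 24 h went from -0.36 to 0, and no other list median there was negative. Which scaling is right was not settled by these data. The medians of the anti-apoptotic and heat shock lists over time and of the ribosomal and proteasome lists at 24 h, none of them called there, changed sign under median centring or quantile normalization (for heat shock from -0.013 to 0.011). Plain _at probe sets, a setting chosen after the data were seen, also kept each count within 1.5 times its main value, except for probe sets 2-fold apart in the mutant array (26 at 24 h and 9 at 0 h, against 41 and 16) and in the doxycycline array at 0 h (15, against 24). Without the filter limma called 0 for time (2030 at an unadjusted p under 0.05), 10 for outcome over both times (9 higher, 1 lower), 192 at 24 h, 126 at 0 h and 245 for the interaction, with 315 and 178 probe sets 2-fold apart in the wild-type array at 24 h and 0 h and 4 lists called for outcome over both times. Of the main calls 6 of 48 at 24 h and 0 of 33 over both times were among these, and the call was lost by 15 of 20 named genes called at 24 h and 113 of 113 for time. The 2-fold counts at 24 h were then 213 for the doxycycline and 216 for the mutant array, against 39 and 41. There 15.4% of probe sets sat at the floor on all arrays, and the prior degrees of freedom fell from 6.26 to 0.73 for time and from 6.63 to 0.74 for the outcome fits. With the filter at the 75th percentile, and so fewer probe sets, the 2-fold counts were 38 and 8. With the floor at the median they gave 18 at 0 h, and 24 were called at 24 h; the cause was not tested. Without the variance trend 11 were called at 24 h and 1 over both times; the cause was not tested. Without the treatment block 514 were called for time, and 563 with a 1.5-fold requirement, which can only lower the count. The 2-fold counts of 105 and 32 became 391 and 160 at 1.5-fold and 30 and 8 at 3-fold, as thresholds do.

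With an estimated correlation 0 lists were called for time, outcome over both times and outcome at 24 h, against 15, 7 and 7. In simulated data with independent genes, that setting found 0 of 10 lists shifted by 0.5 or 1 for time and at 24 h, 9 to 10 shifted by 2 or 3, and 9 to 10 at each shift over both times. The set calls of all 3 comparisons rest on the preset correlation. False calls of the preset setting were counted with independent genes only, so they do not show how it behaves in correlated lists. For shifts of 0.5 or 1 over time and at 24 h the setting had little power; that does not cover G2 and mitosis over time (median -2.76), and the lists called over both times (medians -0.24 to 0.32) moved less than the shifts simulated.

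Leaving out 1 array at a time gave 479 to 1283 calls for time, 0 to 50 for outcome over both times, 45 to 351 at 24 h, 0 to 38 at 0 h and 6 to 43 for the interaction. Of the outcome fits, the effect at 24 h could not be fitted without the wild-type array of 24 h, nor that at 0 h without that of 0 h, nor the interaction without either. Without 1 of the doxycycline or mutant arrays 1 residual degree of freedom was left and the prior degrees of freedom were 18.2 to 898, against 6.63. Of 3039 values of named genes under the alternatives, 2466 kept their side of the threshold, 501 lost the call, 72 gained it and 0 reversed. Signals near the floor of 16.4 limit the size of the changes.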

Other observations

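Few markers of other cell types were measured above the filter, and of the 9 measured none was called by limma over time or for outcome; they are named here in full. Of adipocyte markers, 3 were measured: Cebpa at 838.3 to 1011.9, Lep at 161.0 to 274.1 and Lpl at 146.3 to 293.4. Lpl, lipoprotein lipase, read 290.2 with doxycycline at 0 h and 293.4 at 24 h, and 146.3 to 162.3 in the other 4 arrays. Of macrophage and leukocyte markers, 4 were measured (Cd14, Cd68, Laptm5 and Cd53), with set tests at adjusted p = 0.677 for time and 0.309 for outcome at 24 h; adjusted over the list alone, 1 rose and 1 fell over time. Of endothelial markers only Eng was measured, at 178.3 to 250.3, and of epithelial markers only Cdh1, at 142.7 to 230.8. No bone and cartilage marker of the list passed the filter.

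Krt6a, a stress keratin looked at after its values were seen, read 456.3 with wild-type p300 at 24 h, 145.1 with doxycycline and 119.0 with mutant p300, against 193.6, 123.6 and 104.9 at 0 h. Its second probe set read 134.8, 53.1 and 40.1 at 24 h. In the wild-type arrays Adgrg1 read 233.7 at 0 h and 296.1 at 24 h, and in the doxycycline arrays 18.6 and 44.4. Mapt read 105.5 at 0 h and 491.0 at 24 h with wild-type p300.

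As a hypothesis, with a test chosen after the result was seen, the 81 probe sets at least 2-fold higher with wild-type p300 at 24 h may reflect expression that was kept with wild-type p300 and lost with both other treatments. The median change over 24 h of the 81 was -0.292 with doxycycline and mutant p300 and 0.501 with wild type, with 67 higher at 24 h in wild type, 53 lower in the others and 39 both. The genes had been chosen for a high wild-type value at 24 h, which pushes both medians that way. Among the 21 chosen at 0 h instead, a choice that pushes the medians the other way, they were 0.423 with wild type and 0.159 in the others. The hypothesis asked for a fall of the median in the others past a set limit. The -0.292 of the 81 fell just short of that limit, and the median of the 21 rose. It also asked for a wild-type median under 0.1. The 81 cannot answer that because of how they were chosen, and the 21 lay above it, so the hypothesis is undecided.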
